A study of Arabidopsis thaliana with 4 samples.

How the data were processed

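Total RNA of 14-day-old Arabidopsis seedlings grown in long days at 22 °C was sequenced with paired reads of 150 nt. Per the labels, the 4 genotypes were WT (Col-0), hda6, ldl1/2 and hda6/ldl1/2. HDA6 is a histone deacetylase, and LDL1 and LDL2 are histone demethylases related to human LSD1. GEO lists 1 sample for each genotype, so no spread between replicates could be computed and no test between samples was run here. The hda6 and ldl alleles are not named in the sources used here. The submitters' processing notes name Bowtie and TAIR10.

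The files used were 3 tables of the authors' own comparisons, each of 1 mutant with WT and each with 34262 genes. The authors' tables give the larger of both group means, in deposited RPKM (reads scaled to exon length and library size), beside a log2 fold change, a signed fold change, a p-value and an FDR. The unit is not in the headers and was read from the values, since low means fell on steps of whole reads per exon length. The deposited FDR matched a Benjamini-Hochberg adjustment over all 34262 genes, the 9357 without a fold change included, to within 9.13e-05. The authors' test is not named in the sources used here. Values from these tables are printed as the authors' values, without an error or replicate number. In the text, "rose", "fell" and "changed" are used only of genes with a deposited FDR under 0.05 or, where the sentence says so, of genes under 0.05 when adjusted over the list alone.

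Genes were matched by position to the TAIR10.1 reference annotation. A single reference gene matched 33191 of the tables' genes, several matched 32 and none matched 1039. All 19493 locus names that could be compared matched. Whether the authors' gene models differ in other ways was not tested. Positions are given on TAIR10.1.

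The depth was worked out from the smallest means. With a tolerance of 0.3%, 99.6% of 741 low WT values fell on whole-read steps of 3 libraries of 48.6 to 51.6 M reads. Low values of each mutant group fell on steps of 2 libraries, at 47.3 and 47.5 M reads for hda6, 40.2 and 42.6 M for ldl1/2, and 43.8 and 49.4 M for hda6/ldl1/2. On shifted steps the share was at most 21.9%. The tables therefore appear to average more libraries than the 1 sample per genotype that GEO lists. What these libraries were (separate plants, or repeat libraries of 1 sample) is not given in the sources used here, so the authors' p-values measure a spread which may be technical. The standard error that the authors' p-values imply was 0.32 in log2 in the hda6 table at 1 to 2 RPKM and 0.12 at 10 to 50 RPKM. Floors and counting intervals below cover counting error only.

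The main value is the log2 fold change as deposited. The design fixed before the data were seen had assumed values per library and a pseudocount of 1, which these tables do not hold, so the pseudocount of 1 was run as an alternative on group means rebuilt from the tables. WT means could be read directly for 12654 genes in at least 1 comparison, and were identical wherever more than 1 comparison gave them. A gene was kept in a comparison with a larger group mean of at least 1 RPKM, and it counted as higher or lower by a rule of size, a log2 fold change at or beyond 1 or -1. Where the rebuilt lower mean was under 0.5 reads over the group, the fold is given as a lower bound against a floor of 3 reads over the group. Where it was at or above 0.5 reads and rounded to 1 to 3 reads, an exact Poisson interval (95%) for those reads is given. The tables print only the larger mean, so a WT level near 0 is inferred from the fold change.

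The 22 gene lists (288 entries) were fixed before the data were seen. Each list median was placed among 10000 random lists of the same size, matched on expression. This percentile describes these libraries and is no test. The counts of list members past the FDR are given over all genes and adjusted over the list alone. A further 3 lists (42 entries) for sulfur, phosphate and iron were chosen after values of several members had been seen. Overlaps were compared with n1 × n2 / N and with 100 simulated sets of unchanged mutants that share the WT mean, whose noise came from the standard errors above. That noise may be technical, so the simulation does not cover differences between plants, nor a deviation of the WT sample that serves all 3 comparisons. Overlaps were first computed over genes kept in every comparison. They were recomputed over the 19410 genes kept in at least 1 comparison after it was seen that the first choice dropped genes silent elsewhere.

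Named genes followed a rule written before the data were seen. It took the targeted genes and, in each comparison, the 8 highest and 8 lowest genes past the size rule of at least 5 RPKM. It also took up to 4 measured members per list, the 6 genes per direction shared most strongly by all 3 comparisons, and the 5 per direction farthest from the sum of the other mutants. Other members of the fixed lists, the neighbours of PUX9 and the members of the added lists were named after their values had been seen.

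The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. It was tested on simulated data. The size rule found 60% of genes changed 2-fold, 98% of genes changed 4-fold and 0% of genes changed 1.5-fold. The step search found the simulated number of libraries in all 4 groups. Of 100 random lists of unchanged genes, 4% fell outside the central 95%. The alternatives were other pseudocounts, filters, scalings and size rules, the authors' FDR with and without the size rule, and the narrower gene set for overlaps. The libraries are not stated to be strand-specific, and reads of near-identical copies (the LHCB1, PDF1.2 and beta-galactosidase related genes) may be shared between them.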

Results

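The series compares the transcriptomes of seedlings labelled hda6 (a histone deacetylase gene), ldl1/2 (a pair of histone demethylase genes) and hda6/ldl1/2 with WT. In ldl1/2 both targeted transcripts fell, with log2 fold changes in the authors' deposited table of -0.79 for LDL1 (AT1G62830, chromosome 1, 23264486 to 23267221, FDR 2.52e-05) and -1.17 for LDL2 (AT3G13682, chromosome 3, 4478873 to 4481767, FDR 0.000182). In the samples labelled hda6/ldl1/2 neither fell, with 0.05 for LDL1 and -0.32 for LDL2 (FDR 0.585) in the authors' deposited table. HDA6 (AT5G63110, chromosome 5, 25315506 to 25318347) rose in hda6 by 0.53 (FDR 0.000179) and in the samples labelled hda6/ldl1/2 by 0.59 (FDR 1.03e-05) in the authors' deposited table. No targeted transcript was thus lower in the samples labelled hda6/ldl1/2 past the deposited FDR, nor HDA6 in hda6. A transcript level does not show whether a protein works and the alleles are not named in the sources used here, so every direction below is given for the samples as labelled.

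In hda6, some genes that were nearly silent in WT were expressed, while genes of the immune response fell. Among the largest increases, with bounds computed from the authors' deposited table, were those of AT3G44265, which encodes a beta-galactosidase-like protein and was at least 3544-fold higher (63.7 RPKM), AT5G41660 (at least 2392-fold) and AT4G08691 (at least 2064-fold), each against a floor of 3 reads over the WT group. SDC, an F-box gene silenced by DNA methylation in WT, reached 1.34 RPKM in the authors' deposited table, which by the same floor is at least 110-fold higher. Of 17 genes annotated as beta-galactosidase related or beta-galactosidase-like, a group singled out after its values were seen, 10 passed the expression filter in hda6 and 7 were higher by the size rule. Low genes pass that filter through the group in which they are higher, and near-identical copies may share reads. Of the 381 genes higher by the size rule, 268 had a rebuilt WT mean under 1 RPKM and 98 (25.7%) one under 0.1 RPKM.

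Among the 23 measured salicylic acid and immune response genes, 20 fell in hda6 in the authors' deposited table and 21 did when adjusted over the list alone; none rose, and the list median was -1.36. PR1, a marker of salicylic acid signalling, had a log2 fold change of -11.78 in the authors' deposited table, resting on about 2.27 reads over the hda6 group (computed here as 1148-fold to 34240-fold lower by counting error). Decreases were also large for PR2, a glucanase (-4.93), PAD3, the last enzyme of camalexin synthesis (-4.20), and FMO1, which makes N-hydroxypipecolic acid (-4.36), in the authors' deposited table. By the floor of 3 reads GSTU3, a glutathione transferase, was at least 190-fold lower, computed from the authors' deposited table. CAD8, an alcohol dehydrogenase, fell by 9.40 in the authors' deposited table. Jasmonate and ethylene response genes had a median of -0.33, with 5 of 20 lower and none higher past the deposited FDR (8 lower when adjusted over the list alone), among them the tyrosine aminotransferase TAT3 at -7.85 in the authors' deposited table.

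Nuclear photosynthesis genes went the other way in hda6: 11 of 20 rose and none fell in the authors' deposited table (14 rose when adjusted over the list alone), with a median of 0.35. The light-harvesting genes LHCB2.1 and LHCB3 rose by 1.26 and 0.94, while the Rubisco small subunit gene RBCS1A stood at 0.03 in the authors' deposited table. Darkness and starvation markers were also higher in hda6, where 3 of 3 measured rose in the authors' deposited table, as when adjusted over the list alone, with a median of 0.77. The remaining member, DIN2, was below the expression filter in hda6 and stood at -1.55 (FDR 0.0593) in the authors' deposited table. Of the clock genes, 2 of 6 morning and 4 of 13 afternoon and evening genes rose and none fell in the authors' deposited table (3 and 4 when adjusted over the list alone), with medians of 0.24 and 0.16. The flowering repressors MAF4 and MAF5 rose by 2.73 and 2.70 in the authors' deposited table, whereas their relative FLC stood at 0.38 (FDR 0.655). Of 12 flowering repressors measured, these 2 rose and none fell past the deposited FDR, and the same 2 were found when adjusted over the list alone. Within the silencing machinery, ROS1, a DNA demethylase, fell by 1.46, IBM1, a histone demethylase, by 0.58 and RDR6, an RNA-dependent RNA polymerase, by 0.49, while NRPE1, the largest subunit of RNA polymerase V, rose by 0.56 in the authors' deposited table. The other 12 of its 16 measured members did not pass the deposited FDR, and adjusting over the list alone gave the same 3 lower and 1 higher. Among the largest decreases was that of PUX9 (AT4G00752, chromosome 4, 317564 to 320935), a gene for a UBX domain protein, which by the same floor was at least 725-fold lower in hda6 but stood at -0.12 in ldl1/2 and -0.24 in the samples labelled hda6/ldl1/2 in the authors' deposited table.

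By the size rule 381 of 18985 expressed genes were higher in hda6 and 380 were lower. Of these, 353 and 338 also had a deposited FDR under 0.05 in the authors' deposited table. With a pseudocount of 1, which weighs against genes of low expression, the counts were 224 higher and 239 lower.

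In ldl1/2 the glucosinolate genes fell, and genes of anthocyanin synthesis and some plant defensins rose. Of 11 glucosinolate genes measured, 10 fell and none rose in the authors' deposited table, all 11 fell when adjusted over the list alone, and the median was -1.45. MYB29, a transcription factor of aliphatic glucosinolate synthesis, fell by 2.26, BCAT4, an enzyme of methionine chain elongation, by 2.18 and MAM1, a methylthioalkylmalate synthase, by 1.69 in the authors' deposited table. In hda6 and the samples labelled hda6/ldl1/2 the list medians were 0.06 and 0.23. The homocysteine S-methyltransferase gene HMT3 fell 8.02-fold in ldl1/2 in the authors' deposited table.

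Of 14 flavonoid and anthocyanin genes measured in ldl1/2, 7 rose and none fell in the authors' deposited table, 9 rose when adjusted over the list alone, and the median was 0.45. The late enzymes DFR and LDOX rose by 3.84 and 3.63 in the authors' deposited table. Their regulators PAP1 and PAP2 rose by 2.39 and 2.56, while the early enzyme CHS stood at 0.35 (FDR 0.221), in the authors' deposited table. Of 12 flavonoid genes measured in hda6, 2 rose and 1 fell in the authors' deposited table, as when adjusted over the list alone. DFR and LDOX rose there by 1.53 and 1.67, and PAP2 fell with a log2 fold change of -2.549, in the authors' deposited table. In ldl1/2 the defensin genes PDF1.2A, PDF1.2B and PDF1.2C, close copies that may share reads, rose by 3.10, 3.17 and 3.67 in the authors' deposited table. In the whole jasmonate and ethylene list 5 of 20 rose and 4 fell in the authors' deposited table (7 and 4 when adjusted over the list alone), with MYC2, a jasmonate transcription factor, at -1.98.

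Flowering repressors in ldl1/2 went both ways, with 3 of 12 higher and 2 lower past the deposited FDR in the authors' deposited table, as when adjusted over the list alone, and a median of -0.05. FLC rose by 1.69, MAF4 by 1.62 and MAF5 by 3.05 in the authors' deposited table, while TEM2, another repressor of FT, fell by 0.97. The florigen gene FT fell by 1.38, SPL3 by 1.37 and SOC1 by 0.43 in the authors' deposited table, whereas FUL, also an activator of flowering, rose by 0.92. Of 9 flowering activators measured 4 fell and 1 rose in the authors' deposited table (5 and 2 when adjusted over the list alone), with a median of -0.43. Photosynthesis genes had a median of -0.29 in ldl1/2, and 8 of 20 fell and none rose in the authors' deposited table (11 fell when adjusted over the list alone), with LHCB1.1 at -1.02. Of 4 darkness and starvation markers 3 fell and 1 rose in the authors' deposited table, as when adjusted over the list alone, with SEN1 at -1.43 and a median of -0.98. Clock genes were also lower on balance, with 1 of 6 morning and 3 of 13 afternoon and evening genes lower and none higher in the authors' deposited table (2 and 4 lower when adjusted over the list alone), and medians of -0.30 and -0.11. Immune genes had a median of -0.18, with 4 of 23 lower and 2 higher past the deposited FDR in the authors' deposited table (9 and 3 when adjusted over the list alone).

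By the size rule 321 of 18928 expressed genes were higher in ldl1/2 and 276 were lower. Of these, 260 and 237 also had a deposited FDR under 0.05 in the authors' deposited table, and a pseudocount of 1 left 163 and 150.

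**Figure D1:**
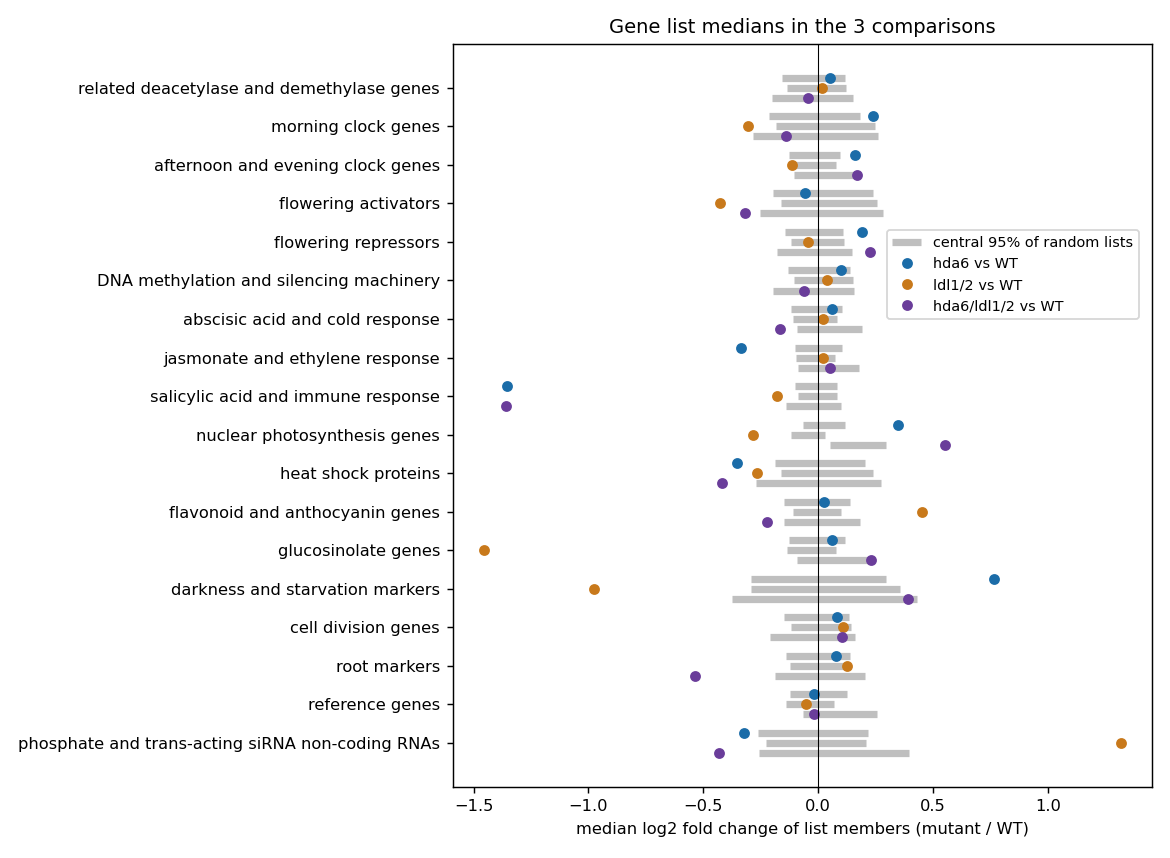
Median log2 fold change (x axis, mutant over WT) of 18 gene lists fixed before the data were seen, 1 point per comparison, with grey bars for the central 95% of 10000 random lists matched on expression. Immune genes lie at -1.36 in hda6 and hda6/ldl1/2, and glucosinolate genes lie at -1.45 in ldl1/2.

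In the samples labelled hda6/ldl1/2 several genes nearly silent in WT and some flowering repressors were higher. AT3G44265 was at least 3538-fold higher, computed from the authors' deposited table against the same floor of 3 reads over the WT group. FWA, a flowering repressor silenced by DNA methylation in WT, rose by 7.50 in the authors' deposited table, resting on about 2.38 reads over the WT group (computed here as 55.2-fold to 1645-fold by counting error). On the same WT reads FWA rose in ldl1/2 (6.01-fold to 179-fold by counting error) and was higher without passing the FDR (0.503) in hda6 (1.32-fold to 39.2-fold), at 0.117 and 0.0256 RPKM in the authors' deposited table, below the expression filter in both. FLC, MAF4 and MAF5 rose by 2.53, 3.23 and 4.24 in the authors' deposited table. Of 13 flowering repressors measured, 6 rose and 2, TEM1 (-0.62) and TEM2 (-0.72), fell in the authors' deposited table, as when adjusted over the list alone, with a median of 0.22. APOLO, known as a long non-coding RNA locus near PID, rose by 5.48 to 126 RPKM, against 1.76 in hda6 and 2.18 in ldl1/2 in the authors' deposited table. FUS3, a regulator of seed maturation, rose by 5.75 in the authors' deposited table. It also rose by 4.18 in hda6 and 4.19 in ldl1/2 in the authors' deposited table, though at 0.461 and 0.492 RPKM it was below the expression filter there.

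Immune genes in the samples labelled hda6/ldl1/2 had a median of -1.36, and 19 of 23 fell and none rose in the authors' deposited table (20 fell when adjusted over the list alone). PR2 (-3.58), PAD3 (-4.31) and SARD1, an activator of salicylic acid synthesis (-2.37), were among them in the authors' deposited table. Photosynthesis genes had a median of 0.55, with 15 of 20 higher and none lower in the authors' deposited table, as when adjusted over the list alone. Of the clock genes, 1 of 6 morning and 5 of 13 afternoon and evening genes rose and none fell in the authors' deposited table, as when adjusted over the list alone, with medians of -0.14 and 0.17, and 1 of 3 darkness markers rose and 1 fell, with a median of 0.39. Root markers had a median of -0.54, and 5 of 13 fell and none rose in the authors' deposited table (7 fell when adjusted over the list alone), with CASP1, a Casparian strip gene, at -1.18 and PHT1;1, a phosphate transporter, at -0.99. Root medians were 0.08 in hda6 and 0.12 in ldl1/2.

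The cold-regulated gene COR15A rose by 3.08 in the samples labelled hda6/ldl1/2 and by 2.06 in hda6 in the authors' deposited table. In the whole abscisic acid and cold list 6 of 18 rose and 4 fell in the authors' deposited table (7 and 4 when adjusted over the list alone), with a median of -0.17. Flavonoid genes split: DFR and LDOX rose by 3.38 and 3.30, while CHS, F3H and FLS1 fell by 0.53, 0.52 and 0.51 in the authors' deposited table. Altogether 4 of 14 flavonoid genes rose and 7 fell in the authors' deposited table (5 and 7 when adjusted over the list alone). By the size rule 646 of 19052 expressed genes were higher and 503 were lower, a balance that turned under the RPKM ratio (561 and 644), the nuclear total (574 and 603) and 5 times the expression filter (215 and 223). Of the 646 and 503, 598 and 470 also had a deposited FDR under 0.05 in the authors' deposited table, and a pseudocount of 1 left 382 and 264.

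**Figure D2:**
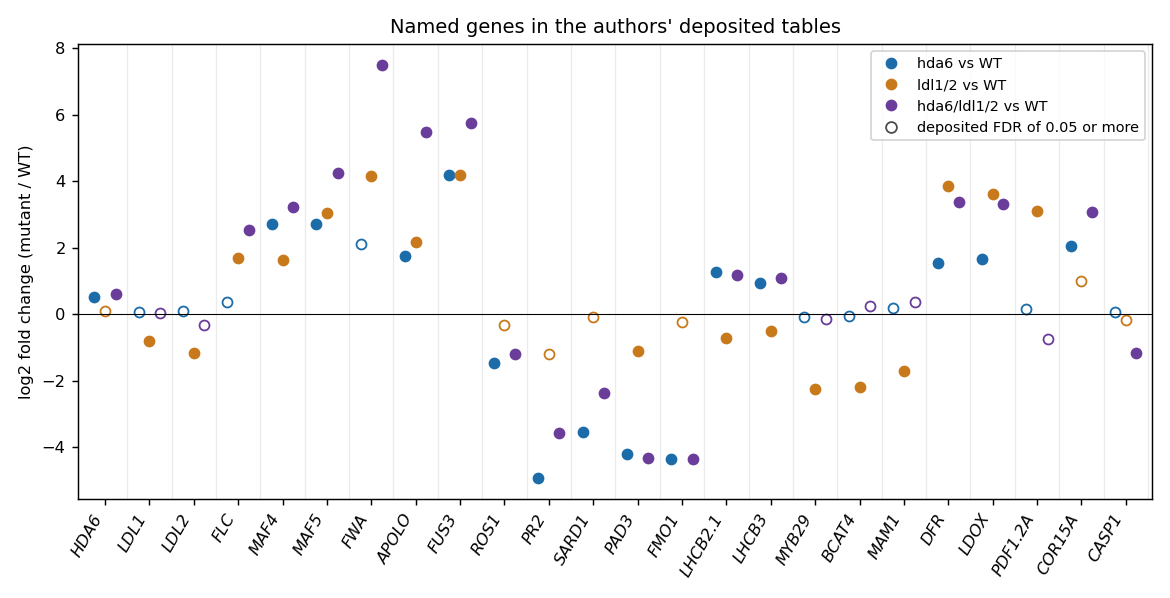
Log2 fold changes (y axis, mutant over WT) of 24 named genes as the authors deposited them, with filled points for a deposited FDR under 0.05 and open points for the rest. LDL1 and LDL2 are filled below 0 in ldl1/2 alone, at -0.79 and -1.17.

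The share of genes past the size rule was also counted by transcript class. Of expressed lncRNA genes 8.57% (12 of 140, exact Clopper-Pearson interval 4.51 to 14.5%) were higher in hda6, 3.70% (5 of 135, 1.21 to 8.43%) in ldl1/2 and 12.5% (18 of 144, 7.58 to 19.0%) in the samples labelled hda6/ldl1/2. The share of protein-coding genes was 1.92%, 1.61% and 3.17%. As a gene passes the filter through its higher group, low genes enter these shares when they rise, so shares of classes of different expression are not compared further. Of 35 expressed plastid genes 21 (60%, 42.1 to 76.1%) were higher in the samples labelled hda6/ldl1/2, against 4 of 30 in hda6 and 9 of 31 in ldl1/2. The intervals treat genes as independent draws and cover no spread between plants, and the class shares were not run under the other scalings. Genes annotated as tRNA, miRNA, snoRNA, snRNA and rRNA had no deposited fold change in any comparison, and 321 of 3447 lncRNA genes had one. Whether the authors counted reads of these classes is not given in the sources used here.

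A total of 51 genes were higher and 68 lower by the size rule in all 3 comparisons. Lists drawn independently from the 19410 genes would share 0.21 and 0.14, and unchanged mutants sharing the WT mean shared 0.01 and 0.02 on average. The noise of these simulated mutants may be technical, so a deviation of the WT sample, which all 3 comparisons share, is not covered. Among the genes shared were the uncharacterized AT1G27565, with log2 fold changes of 6.11 in hda6, 5.60 in ldl1/2 and 6.36 in the samples labelled hda6/ldl1/2 in the authors' deposited table, and the non-coding AT4G04223, with 3.82, 3.96 and 3.86. Among the shared decreases were BAP2, a suppressor of cell death (-4.77, -3.43 and -5.09), and ABCG40, an abscisic acid importer (-3.70, -2.58 and -4.35), in the authors' deposited table. Between hda6 and ldl1/2, 53 genes were higher in both and 73 lower in both, against 6.30 and 5.40 for independent lists, while 32 were lower in hda6 and higher in ldl1/2 against 6.28, and 7 were higher in hda6 and lower in ldl1/2 against 5.42.

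More genes of the samples labelled hda6/ldl1/2 were shared with hda6 than with ldl1/2, a difference that was not tested. Of their 646 higher genes 303 were also higher in hda6 (12.7 for independent lists) and 129 in ldl1/2 (10.7). Over genes expressed in every comparison these counts were 135 and 100, so most of the difference among higher genes came from genes under 1 RPKM in another comparison. Of their 503 lower genes 242 were also lower in hda6 (9.85) and 121 in ldl1/2 (7.15). Across 18603 genes, which are not independent replicates, the covariance of the log2 fold changes with those of hda6 was 0.226 and with those of ldl1/2 0.106, against 0.0114 for simulated unchanged mutants sharing the WT mean. The corresponding Pearson r was 0.73 and 0.47, against a simulated 0.40. Between hda6 and ldl1/2 the covariance was 0.0507 and r 0.24, against a simulated 0.0114 and 0.40. The simulated r is that of noise alone, so it is no baseline for data in which genes changed. Regressed on the sum of the separate mutants, the log2 fold changes of the samples labelled hda6/ldl1/2 had a slope of 0.60 and r of 0.78, against 0.285 and 0.477 for simulated unchanged mutants sharing the WT mean. These simulated values too are those of noise alone and are no baseline. The shared WT mean enters both sides of the regression, so the slope does not measure additivity.

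Single genes departed from that sum in both directions. APOLO was 1.54 above it, while AT1G27565 was 5.35 below it, in log2 from the authors' deposited table. AT4G06643, an uncharacterized gene, had 6.25 RPKM in the samples labelled hda6/ldl1/2 and at most 0.0134 RPKM in hda6 in the authors' deposited table, which by the floor of 3 reads is at least 247-fold above WT. Of the 646 higher and 503 lower genes, 265 and 208 passed the expression filter and the size rule together in neither other mutant. FUS3, for example, counts among the 265, as it rose in both other mutants but lay below the filter there. Of the 265 and 208, 25 and 98 lay within 0.5 of 0 in both other mutants. With a pseudocount of 1 in all 3 comparisons, 47 of 382 higher and 27 of 264 lower genes did so. That pseudocount also moves low genes of the other mutants towards 0. A deposited FDR under 0.05 was held by 18 of the 25 and 88 of the 98 in the authors' deposited table. No test of the difference between mutants was run, as the tables hold no values per library.

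**Figure D3:**
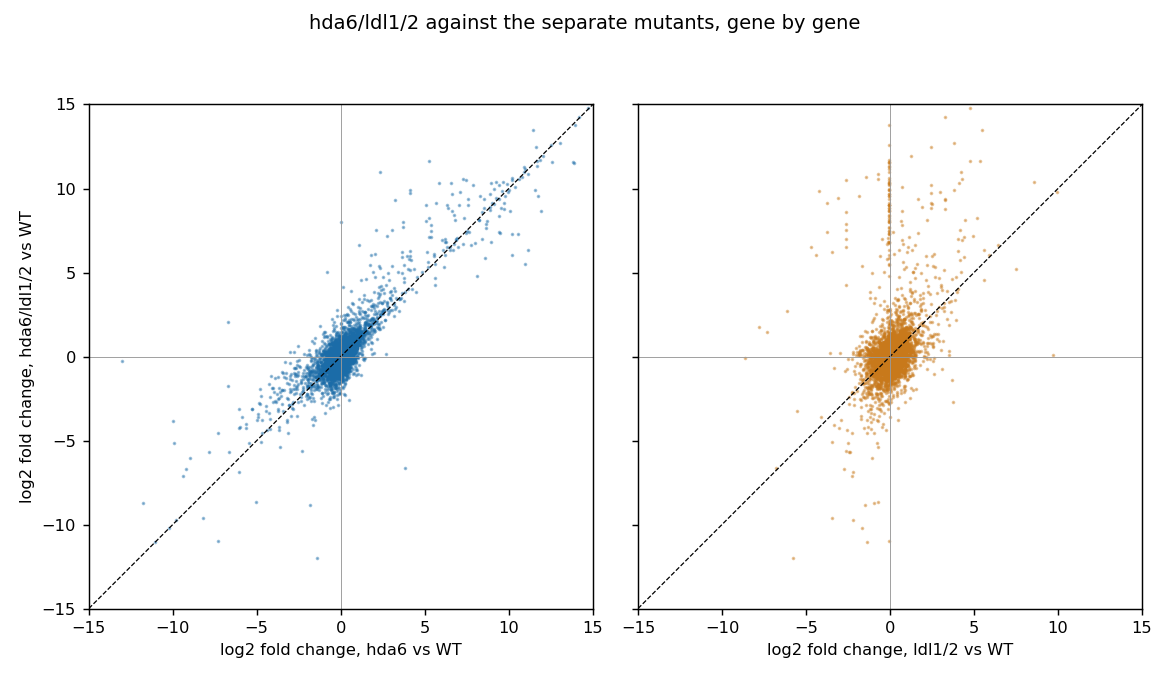
Log2 fold change of hda6/ldl1/2 (y axis) against hda6 (left) and ldl1/2 (right), each over WT, with 1 point for each of 19410 genes at 1 RPKM or more in at least 1 comparison and a dashed line of equal values. Pearson r over the 18603 genes expressed in every comparison was 0.73 for hda6 and 0.47 for ldl1/2.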

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

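The pseudocount of 1 was the design's own choice and was made an alternative after seeing the data, as the tables hold no values per library. The deposited FDR alone was also chosen after seeing the data, and so was the wider gene set used for overlaps in the report, with the narrower first set kept as the alternative. The counts of higher and lower genes stayed within 1.5 times under a pseudocount of 0.1, the 3 other scalings and the size rule plus the deposited FDR. Named genes at 1 RPKM or more were run only under the pseudocounts and scalings, where no direction past the deposited FDR turned. A pseudocount added to both means keeps the sign of a ratio, and the largest shift by a scaling was -0.13 in log2, in hda6/ldl1/2. The lack of turns was therefore largely fixed in advance. In the following, counts are in the order hda6, ldl1/2 and hda6/ldl1/2. A pseudocount of 5 gave 78, 63 and 134 higher and 94, 55 and 87 lower, 8 and 10 in all 3 comparisons, and 14 and 7 near 0 in the separate mutants. A pseudocount of 1 gave 224, 163 and 382 higher and 239, 150 and 264 lower, 19 and 34 in all 3, and 47 and 27 near 0 in the separate mutants. Without a filter the counts were 1837, 1591 and 2452 higher and 1466, 1321 and 1556 lower, 504 and 397 in all 3, and 378 and 189 near 0 in the separate mutants, with a slope on the sum of 0.493. At 5 times the filter they were 122, 145 and 215 higher and 165, 150 and 223 lower, 17 and 28 in all 3, and 4 and 42 near 0 in the separate mutants. A size rule of log2 2 gave 188, 83 and 302 higher and 152, 39 and 135 lower, 13 and 18 in all 3, and 4 and 2 near 0 in the separate mutants. The deposited FDR alone gave 831, 834 and 1827 higher and 818, 774 and 1490 lower, 121 higher in all 3, and 894 and 823 near 0 in the separate mutants. These shifts follow from the rules themselves, which admit more or fewer genes of low expression or small change. Scaling by RPKM alone moved the higher share in hda6/ldl1/2 from 56.2% to 46.6% (561 higher and 644 lower) and the nuclear total moved it to 48.8% (574 and 603), and 5 times the filter moved it to 49.1%, so the excess of higher genes there depended on both the scaling and the filter. At that filter lower genes outnumbered higher genes in all 3 mutants.

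Over genes kept in every comparison, 135 genes instead of 303 were higher in both hda6 and hda6/ldl1/2 and 100 instead of 129 in both ldl1/2 and hda6/ldl1/2. Of the list medians, 2 that lay outside the random lists turned: flavonoid genes in hda6/ldl1/2 to 0.0244 without a filter, and the non-coding RNA list there to 0.10 at 5 times the filter, as other members were admitted or lost. Another 88 values of list medians moved beyond the spread of random lists and 395 did not, and 1601 values of named genes moved beyond the standard error the authors' p-values imply while 3817 did not. Median-ratio scaling replaced the design's size factors, which need counts per library. The read-count filter and a second unit per library were not run for the same reason, and no paired analysis was possible because the tables hold no values per library.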

Other observations

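All tests weighed in this part were chosen only after the result was seen, and so were the sulfur, phosphate and iron lists. In ldl1/2, 14 of 15 sulfur limitation markers rose and none fell in the authors' deposited table (all 15 when adjusted over the list alone), with a median of 1.44. SDI1, a repressor of glucosinolate synthesis under low sulfur, rose by 2.90, the cyclotransferase gene GGCT2;1 by 3.49 and the sulfate transporter gene SULTR1;2 by 1.15 in the authors' deposited table. Of 13 phosphate starvation markers 12 rose and none fell in the authors' deposited table (12 when adjusted over the list alone), with a median of 1.17, among them SPX3 and PS2, both at 3.54. In hda6 SDI1 fell by 1.71 in the authors' deposited table, and the phosphate median was -0.37.

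Iron deficiency markers had a median of 0.70 in hda6, where 6 of 12 rose and none fell in the authors' deposited table (7 when adjusted over the list alone), against medians of -0.29 in ldl1/2 and -0.01 in hda6/ldl1/2. The iron transporter gene IRT1 and the regulator bHLH38 rose by 1.00 and 1.77 in hda6 in the authors' deposited table. Next to PUX9, AT4G00750 fell in hda6 (fold change -2.82) and in ldl1/2 (log2 fold change -0.57) in the authors' deposited table, while AT4G00755 stood at -0.24 in hda6. Cell division genes had no member past the deposited FDR in any mutant in the authors' deposited table, with medians of 0.08, 0.11 and 0.11.

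LDL1 and LDL2 were lower in ldl1/2 and not in the samples labelled hda6/ldl1/2. If those samples were hda6 plants under a wrong label, genes that changed in ldl1/2 and lay near 0 in hda6 would lie as near 0 in them. Over 216 such genes the median was instead 0.51 higher in the ldl1/2 direction than in hda6. Their median in that direction was 1.285 in ldl1/2, by which they were chosen, and 0.48 in these samples. AT5G67120, at 0.149 RPKM or less in hda6, reached 6.56 RPKM in ldl1/2 and 6.73 RPKM in these samples in the authors' deposited table. These values argue against hda6 plants under a wrong label, but do not show that these samples hold the ldl1/2 change in full. The 216 genes were chosen to lie near 0 in hda6, so a part of the 0.51 may come from that choice. Noise of the size that the authors' p-values imply did not account for the LDL1 and LDL2 values either. The smaller of both differences, at LDL2, was 2.45 combined standard errors, not far beyond the bound of 2. That noise may be technical, so differences between plants are not covered. Other alleles or a segregating stock stay open and were not tested.

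Glucosinolate genes were lower in ldl1/2 and not in the samples labelled hda6/ldl1/2. Another harvest time of day cannot be told apart from an effect of the lesions: the median absolute log2 fold change of 19 clock genes was small (0.20), but 4 of them fell and none rose, and the darkness markers had a median of -0.98, while both sets were higher in hda6. Only 6 of 11 morning clock genes passed the expression filter in ldl1/2, so the small clock median leaves out the others. A sulfur limitation of the ldl1/2 plants may also account for the decrease, given the sulfur marker median of 1.44, though 9 of 14 markers rose and none fell in hda6/ldl1/2 too in the authors' deposited table (10 when adjusted over the list alone), where the glucosinolate median was 0.23. The bounds of both tests were tightened after their results were seen, for harvest time to take in the direction of the clock and darkness lists, and for sulfur because the median in hda6/ldl1/2 (0.45) lay within the spread of random lists (0.0658) below the first bound of 0.5. GEO lists 1 sample per genotype and whether the libraries behind the means were separate plants is not given in the sources used here, so growth conditions cannot be told apart from genotype.

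Immune genes were lower in hda6 and in the samples labelled hda6/ldl1/2. If the shared WT libraries alone had raised immune expression, the list would be about as low in ldl1/2. Its median there was 1.18 above that of hda6, so a raised WT alone does not account for the whole pattern. A raised state shared by WT and ldl1/2 would give the same values and cannot be told apart, as GEO lists 1 sample per genotype. A raised WT alone may still account for a part, as PAD3, CYP71A13, ALD1 and WRKY40 also fell in ldl1/2, PAD3 with a log2 fold change of -1.11, in the authors' deposited table. Of the 23 measured genes, 2 rose in ldl1/2, WRKY54 by 1.39 among them, in the authors' deposited table. Whether the plants met a pathogen or differed in growth conditions was not tested.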
